A study of Mus musculus with 4 samples.

How the data were processed

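Single-cell RNA libraries were made with the 10x Chromium Single Cell 3′ v3 kit from the stromal vascular fraction of the fourth inguinal depot of 8-week-old C57BL/6 mice, after 24 h at 4 °C (2 libraries) or at room temperature (2 libraries). Per the labels, minced tissue was digested with collagenase for 40 min at 37 °C, passed through a strainer and treated with a lysis buffer against red blood cells. The temperature of the room, the sex of the mice and the number of animals behind each library are not given in the sources used here. The values are raw UMI counts per gene and cell barcode, as deposited by the authors, who made them with Cell Ranger 3.0.2 per the file headers and the processing notes. The notes name the builds mm10 and GRCm38, and Seurat with no version; the annotation release is not given in the sources used here. The files hold 31053 genes and only barcodes with at least 500 UMIs, and no annotation of cells by the authors was used here. Gene positions were taken from the GENCODE annotation on GRCm38 by Ensembl identifier, which matched all 117 identifiers looked up.

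The libraries held 4840 and 3871 barcodes in cold and 6339 and 4168 at room temperature, with 35198164 to 55160902 UMIs each. Cells were kept with at least 500 genes and under 15% mitochondrial UMIs, which left 4061, 3045, 5471 and 3144. Doublets were scored against simulated doublets (the Scrublet method, written anew in Python 3.11.15), and the cells with the highest scores were removed at a rate of 0.8% per 1000 cells, 132, 74, 239 and 79 cells. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 nearest neighbours gave a graph for Leiden clustering at resolution 1, with no batch correction (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2). A cluster took the name of a cell type if at least 3 of its fixed markers were detected in at least 10% of the cluster's cells at a log2 level of 1 or more above the median cluster (pseudocount 5 CPM). A further type within a log2 margin of 1 made the cluster mixed, and a cluster whose 10 leading genes, each detected in 25% of its cells, held more markers of another type stayed unnamed, as did one with low UMIs and no own marker among them. The markers were fixed in advance, but the thresholds for naming were set with the data at hand. The comparison with the median cluster replaced one with all other cells after the clusters had been seen, since 1034 cells led by Prlr had first stayed unnamed. The 1066 cells in mixed or unnamed clusters were left out of the classes. A class was tested if each library held at least 20 of its cells; basal/myoepithelial cells had 19 in cold replicate 2 and were not tested.

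Raw counts were summed per class and library, and each class was tested alone with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr, the quasi-likelihood fit and two-sided F-test of cold against room temperature, and Benjamini-Hochberg adjustment within the class at 0.05. Classes of first interest, from the title of the study, were the hormone-sensing, alveolar, basal and fibroblast classes. Shares of cells were tested with the edgeR quasi-likelihood test on cell numbers with the library total as offset. The difference in cold effect between classes was tested as an interaction with the library as block. Gene lists, 29 in all, were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation. No test across cells was used, since cells of a library are not replicates. The tests, alternatives, markers, lists and the rule for named genes were chosen before the data were examined. Per class of first interest the rule takes the 10 largest changes each way among genes past the threshold, with a mean of at least 20 CPM and all cold libraries on the same side of all room-temperature libraries, and up to 4 called members per list, besides a few genes fixed by name. Some genes these rules pick are not reported here. Other classes give 4 each way and interaction tests 5 each way. Predicted, ribosomal and mitochondrial genes were left out, as were symbols that occur more than once. Xist and the Y-linked Ddx3y, Uty, Kdm5d and Eif2s3y were left out too, while other X-linked genes were kept. A gene was noted as possible free RNA where its highest library CPM in the class lay under 5% of the mean CPM in the class that holds most of it.

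The alternatives were a replicate block, DESeq2 1.42.0, RLE scaling, no low-count filter, doublets kept, a looser filter (200 genes, 25% mitochondrial), Leiden resolution 2, an estimated correlation for lists, TMM scaling or lymphocytes left out of the total for shares, and leaving out each library in turn. With a library left out, its group's lone library is assumed to vary like the others. Alternatives added after the data were seen left out possible free RNA genes, kept the largest hormone-sensing cluster alone, or left out hormone-sensing cells with 2 or more alveolar marker UMIs per 10000. Simulated data gave each gene of a class the same estimated dispersion and let genes vary independently. The recovery holds for that setting and can be lower where genes differ in spread or move together. On these data edgeR recovered 21.2% of changes of log2 1 and 87.0% of log2 2 in hormone-sensing cells. It recovered 27.1% and 94.0% in alveolar progenitors and 76.8% and 99.0% in fibroblasts. The interaction tests recovered 45.9%, 68.0% and 73.0% of log2 2 changes for hormone-sensing against alveolar, hormone-sensing against fibroblast and alveolar against fibroblast cells. The share test was simulated for the alveolar class at a fixed coefficient of variation of 0.2, not one estimated from the shares. It found a log2 change of 2 in 92.5% of 40 runs, with 7 false calls. The SE of the real share changes ran from 0.36 to 0.70, so this recovery need not hold for them. Camera found a simulated list change in each class but the alveolar and NK/innate lymphoid classes, where the list had 3 measured members. Whole-library sums per gene differed between replicates beyond counting error (chi-square per degree of freedom 27.1 in cold and 78.1 at room temperature), which includes differences in the mix of cells. Values within clusters are medians over genes of the log2 ratio of mean CPM plus 1, over libraries with at least 20 cells of the cluster.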

Results

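Single-cell RNA sequencing (10x Chromium 3′ v3) was carried out on the stromal vascular fraction, the cells other than mature adipocytes, of the fourth inguinal fat depot of 8-week-old C57BL/6 mice, which in females surrounds the mammary ducts. The design sets 2 libraries from mice kept for 24 h at 4 °C against 2 libraries from mice at room temperature, and the title places the question in how the ductal epithelium bears on the cold response of fat. Cold replicate 1 held 4840 barcodes with 50988877 UMIs and cold replicate 2 held 3871 barcodes with 37283885 UMIs. Room-temperature replicate 1 held 6339 barcodes with 55160902 UMIs and replicate 2 held 4168 barcodes with 35198164 UMIs. After the filters, 3929, 2971, 5232 and 3065 cells remained in the same order, with median depths of 6771, 7602, 6877 and 7498 UMIs. The 15197 cells formed 39 clusters, from which 13 cell classes could be named by fixed marker genes and 10 had enough cells for a test. Each class name stands for cells like that type by those markers. The labels do not say whether libraries came from separate animals, so p-values measure only the spread between libraries. Levels are means ± SD over the 2 libraries of a group, in CPM of the UMI counts summed per class and library. Changes are log2 fold changes of cold over room temperature from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Each gene said to have risen or fallen lay higher, or lower, in both cold libraries than in both room-temperature libraries. Genome positions are on GRCm38 (mm10). Xist, the X-inactivation RNA of females, stood at 1196, 1146, 1058 and 1264 CPM, and the Y-linked Ddx3y, Uty, Kdm5d and Eif2s3y had 0 to 1 UMIs in each library.

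Which cell types make up more or less of the fraction after cold was asked first. Macrophages and monocytes, marked by Adgre1, C1qa and Csf1r, made up 15.2 ± 1.09% of cells in cold and 30.3 ± 1.09% at room temperature (log2 fold change -0.99, SE 0.36). Luminal hormone-sensing cells, the oestrogen- and prolactin-receptor-bearing cells of the mammary duct (Prlr, Esr1, Pgr), made up 15.0 ± 2.88% of cells in cold and 6.63 ± 2.92% at room temperature (log2 fold change 1.17, SE 0.48). T cells (Cd3e, Cd3d) made up 21.4 ± 4.64% of cells in cold and 11.1 ± 3.55% at room temperature (log2 fold change 0.95, SE 0.44). Basal/myoepithelial cells (Krt14, Krt5), the contractile outer layer of the duct, made up 0.689 ± 0.0697% of cells in cold and 2.05 ± 1.49% at room temperature (log2 fold change -1.55, SE 0.65). Fibroblasts and adipose progenitors (Pdgfra, Dcn) made up 17.0 ± 1.77% of cells in cold and 18.4 ± 10.0% at room temperature. Luminal alveolar progenitors (Elf5, Kit, Csn3), the precursors of milk-secreting cells, made up 2.49 ± 0.433% of cells in cold and 1.78 ± 1.36% at room temperature. None of the 13 shares passed the edgeR quasi-likelihood test after Benjamini-Hochberg adjustment, where the smallest adjusted p was 0.188 and 1 share, that of macrophages, had an unadjusted p under 0.05. An exact permutation test of 2 against 2 libraries cannot go below 0.333. Without room-temperature replicate 1 the basal share (log2 fold change -2.16, edgeR quasi-likelihood adjusted p = 0.0115) and the hormone-sensing share (1.71, adjusted p = 0.0327) passed. A cluster that carried both luminal marker sets was left out of the classes. It held 6.57% and 4.31% of cells in the cold libraries and 2.27% and 4.54% in the room-temperature libraries. Its 644 cells had a median of 42363 UMIs, against 302 cells at a median of 5429.5 in the alveolar class. The alveolar share and changes do not cover it.

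**Figure D1:**
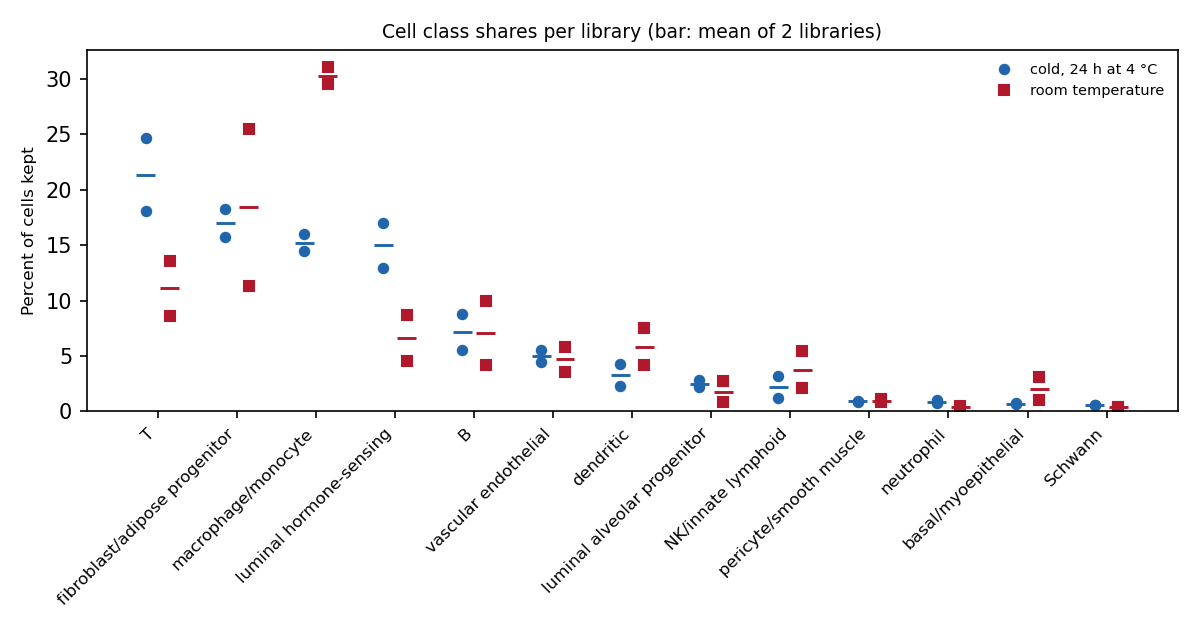
Percent of kept cells in each named class, 1 point per library and a bar at the mean of the 2 libraries of a group. The macrophage/monocyte points lie at 15.98% and 14.4% in cold and at 29.5% and 31.1% at room temperature, and none of the 13 shares passed the test.

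In luminal alveolar progenitors, Angptl4, Ltf and Lrg1, which encode secreted proteins, rose with cold. Angptl4 (ENSMUSG00000002289, chromosome 17, 33773750 to 33781830), a secreted inhibitor of lipoprotein lipase, rose from 17.2 ± 21.4 to 159 ± 41.0 CPM (log2 fold change 3.77, SE 0.61, adjusted p = 0.0045, edgeR quasi-likelihood). Ltf (ENSMUSG00000032496, chromosome 9, 111019271 to 111042767), the iron-binding milk protein lactoferrin, stood at 4341 ± 2991 CPM in cold and 451 ± 129 CPM at room temperature (log2 fold change 3.13, SE 0.40, adjusted p = 9.56e-04). Lrg1 (ENSMUSG00000037095, chromosome 17, 56119678 to 56122001), a secreted glycoprotein, stood at 322 ± 20.5 CPM in cold and 83.1 ± 13.0 CPM at room temperature (log2 fold change 1.81, SE 0.27, adjusted p = 0.0025). Pdk4, a kinase that restrains glucose oxidation, rose by 3.23, the lectin-pathway protease Masp1 by 3.54, the sodium channel subunit Scnn1a by 2.98 and the placental growth factor Pgf by 2.86 on the log2 scale. Acot6 (2.72), Kcne3 (2.63), Shroom1 (2.58) and Papln (2.55) completed the 10 largest increases. Of 6389 genes tested in 43 to 110 cells per library, 90 rose and 41 fell. The cold libraries held 517330 and 383974 UMIs in 110 and 65 cells of this class. The room-temperature libraries held 432876 and 1418417 UMIs in 43 and 84 cells. UMIs per cell were thus lower in both cold libraries, and whether this difference bears on the changes was not tested. Without cold replicate 1 the calls of Masp1 (3.25), Acot6 (2.45) and Shroom1 (2.25) ended, without cold replicate 2 those of Pdk4 (2.38) and Kcne3 (1.94), and without room-temperature replicate 2 that of Pdk4 (2.13). Angptl4 in the luminal alveolar progenitor class stood at 6.02 without room-temperature replicate 1 and 2.11 without replicate 2.

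Among the genes that fell in this class, the neutrophil chemokine Cxcl1 went from 205 ± 219 to 14.2 ± 1.73 CPM (log2 fold change -3.83, SE 0.80, adjusted p = 0.0161, edgeR quasi-likelihood). Tnf stood at 4.54 ± 0.949 CPM in cold and 43.1 ± 24.0 CPM at room temperature. The orphan nuclear receptors Nr4a2 (log2 fold change -2.84, SE 0.42, adjusted p = 0.0025) and Nr4a1 (-1.78) and the immediate early factor Egr3 (-2.94) fell as well. C2cd4b stood at 3.87 ± 5.47 CPM in cold and 96.2 ± 40.4 CPM at room temperature, and Emid1 at 7.81 ± 11.0 CPM in cold and 58.6 ± 7.79 CPM at room temperature. Fabp5, a fatty acid carrier, fell by 2.91 and Stmn1, a microtubule regulator high in dividing cells, fell by 2.76 on the log2 scale. Col3a1 (-3.15), Cd74 (-2.76) and H2-Eb1 (-1.75) fell and Fabp4 (2.50) rose at levels under 5% of those in the class that holds most of each, fibroblasts for Col3a1, dendritic cells for Cd74 and H2-Eb1 and vascular endothelium for Fabp4. The count of 131 changed genes was 61 with DESeq2, 31 at Leiden resolution 2 and 349 without the low-count filter. It was 83 without cold replicate 1, 267 without cold replicate 2, 230 without room-temperature replicate 1 and 508 without room-temperature replicate 2. Of 35 named genes called here, 19 passed with DESeq2, where Angptl4 did not (adjusted p = 0.735), 16 passed at resolution 2 and 23 without cold replicate 1. Ltf, Lrg1, Scnn1a, Pgf, Papln, Tef, Hlf and Nr4a2 passed in each of these fits and with each other library left out. Of the genes that fell, Nr4a1 (-1.22) and H2-Eb1 (-1.49), Emid1 and the rise of Fabp4 (1.01) lost their calls without cold replicate 1, Tnf without room-temperature replicate 1 and H2-Eb1 (-1.56) without room-temperature replicate 2.

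Of the gene lists tested in these cells, 9 were called. Of 11 circadian clock genes measured, 6 rose over all genes tested and 8 rose when adjusted over the list alone, among them the clock-output factors Tef (2.17), Dbp (1.99) and Hlf (1.76) and the repressor Bhlhe41 (1.82). The median log2 fold change of that list was 1.36 (camera adjusted p = 1.62e-11, adjusted p = 0.359 with an estimated correlation). Of 10 milk and secretory genes, 2 rose and 5 did so when adjusted over the list alone. They were led by Ltf and by Lalba, the lactose synthase cofactor, at 118 ± 87.4 CPM in cold and 23.0 ± 16.5 CPM at room temperature (list median 0.72, camera adjusted p = 4.17e-08, adjusted p = 0.359 with an estimated correlation). Of 6 secreted metabolic regulators, 3 rose, Angptl4, Lrg1 and the lipid-binding apolipoprotein Apod (2.03). When adjusted over the list alone 3 rose and 1 fell (list median 1.19, camera adjusted p = 6.49e-05, adjusted p = 0.359 with an estimated correlation). That list lost its call without cold replicate 2 (median 0.01) and without room-temperature replicate 2 (0.14), and the milk list without room-temperature replicate 1 (median 0.36). Dbp lost its call without cold replicate 1 (1.18) and Lalba without cold replicate 2.

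Of 20 dissociation and immediate early stress genes, 2 fell, Zfp36 (-1.32), which destabilises cytokine mRNAs, and Fosb (-1.17). In all 9 fell when adjusted over the list alone (list median -0.71, camera adjusted p = 7.22e-08, adjusted p = 0.359 with an estimated correlation). The cAMP-response list (3 of 11 fell; 1 rose and 5 fell when adjusted over the list alone) and the inflammatory cytokine list (3 of 4 fell; 4 when adjusted over the list alone), with the adhesion molecule Icam1 at -1.96, were also lower. Their medians were -0.61 and -2.56, each with adjusted p = 0.359 with an estimated correlation. The antigen-presentation (MHC class II) list fell in 2 of 4 members and in 4 when adjusted over the list alone (adjusted p = 0.359 with an estimated correlation), all at the low levels given for Cd74. The list for adipocyte differentiation was higher (1 of 5 rose, 2 when adjusted over the list alone; adjusted p = 0.359 with an estimated correlation), its called member being Fabp4. The oxidative phosphorylation list was lower at a median of -0.26 with 0 of 23 members past the edgeR threshold over all genes or adjusted over the list alone (adjusted p = 0.694 with an estimated correlation). Among glucocorticoid-response genes, Pdk4, Klf9 (1.60) and the glucocorticoid-receptor co-chaperone Fkbp5 (1.22) rose, and when adjusted over the list alone 6 of 15 rose and 3 fell, with no call for the list (camera adjusted p = 0.106). Without cold replicate 1 the calls of Zfp36 (-1.30), Fosb (-1.38), Klf9 (1.41) and Fkbp5 (1.11) and of the adipocyte (median 0.36) and oxidative phosphorylation (-0.19) lists ended. Without cold replicate 2 those of Zfp36 (-1.35) and Fosb (adjusted p = 0.161) and the adipocyte list (0.45) ended, and without room-temperature replicate 1 those of the adipocyte (0.09) and oxidative phosphorylation (-0.09) lists.

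In fibroblasts and adipose progenitors, several genes of the extracellular matrix fell with cold, and several heat shock and glucocorticoid-response genes rose. Col3a1 (ENSMUSG00000026043, chromosome 1, 45311538 to 45349706), which encodes fibrillar collagen III, fell from 12742 ± 1186 to 2477 ± 1074 CPM (log2 fold change -2.33, SE 0.29, adjusted p = 0.0209, edgeR quasi-likelihood). Postn, the matrix protein periostin, stood at 443 ± 145 CPM in cold and 2145 ± 329 CPM at room temperature (log2 fold change -2.24, SE 0.24, adjusted p = 0.0192). Ddit4 (ENSMUSG00000020108, chromosome 10, 59949669 to 59951834), a stress-induced inhibitor of mTORC1, rose from 14.4 ± 2.12 to 108 ± 54.6 CPM (log2 fold change 2.87, SE 0.35, adjusted p = 0.0209). Hspa1a (ENSMUSG00000091971, chromosome 17, 34969190 to 34972156), an inducible HSP70 chaperone, rose from 104 ± 7.17 to 721 ± 109 CPM (log2 fold change 2.84, SE 0.18, adjusted p = 0.0084). Its near-identical copy Hspa1b rose by 2.48, with the split of reads between both copies uncertain. Of 11610 genes tested, 135 rose and 201 fell. Leaving out cold replicate 1, Ddit4 and Hspa1a kept their calls, and Col3a1 (-1.96), Postn (-1.96) and Hspa1b (2.61) did not pass.

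The other large increases, over all clusters of the class together, were the B-cell chemokine Cxcl13 (3.30), the retinoic acid hydroxylase Cyp26b1 (2.97), Pdk4 (2.54), the IGF carrier Igfbp3 (2.35), Cyp2f2 (2.23), Galnt15 (2.06) and the lubricin gene Prg4 (2.05). Cxcl13 and Igfbp3 are leading genes of a cluster found mostly in the cold libraries, with no test run within clusters. The largest decreases were the metalloprotease Adam12 (-3.50), the proteoglycan Sdc1 (-2.71), the collagens Col18a1 (-2.37), Col15a1 (-2.33) and Col5a3 (-2.11), the actin-bundling Palld (-2.13), Fbln7 (-2.10) and Maged2 (-1.97). Cirbp, a cold-inducible RNA-binding protein, rose from 64.7 ± 8.86 to 129 ± 12.5 CPM (log2 fold change 1.05, SE 0.12, adjusted p = 0.0206, edgeR quasi-likelihood). Rbm3, another such protein, did not pass (log2 fold change 0.65, SE 0.14, adjusted p = 0.0621). Leaving out cold replicate 1, Col18a1 was the 1 gene among these that passed; the change was at 2.17 for Cxcl13, -2.60 for Adam12 and 1.12 for Cirbp. Cirbp also lost its call without cold replicate 2 (0.99), and Cxcl13 without room-temperature replicate 1 (3.65) or 2 (3.04).

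Of 23 extracellular matrix genes measured in these cells, 13 fell and 19 fell when adjusted over the list alone, with a list median of -1.14 (camera adjusted p = 8.16e-34, adjusted p = 0.367 with an estimated correlation). Within each of the 6 clusters of the class, the median log2 ratio of the matrix genes was below 0, from -0.95 to -0.60. No test was run within clusters, and the values of the Cxcl13-led and Igfbp6-led clusters rest on 3 libraries. The cluster led by Col3a1 and Postn held 7.5% and 8.3% of the class in cold and 20.6% and 27.9% at room temperature. The falls over the whole class therefore include a change in its mix of clusters. The clusters led by Pi16 and by Cxcl13 were the 2 largest of the class in both cold libraries, while the Cxcl13-led cluster was the smallest in both room-temperature libraries. The 7 stress genes that rose of 20 (13 when adjusted over the list alone) included the HSP40 chaperone Dnajb1 (2.01) and the phosphatase Dusp1 (adjusted p = 0.0233). The list had a median of 0.99 (camera adjusted p = 7.55e-25, adjusted p = 0.367 with an estimated correlation). Of 17 glucocorticoid-response genes, 9 rose and 13 rose when adjusted over the list alone. Among them were Ddit4, Pdk4, the glutamine synthetase gene Glul (1.65) and the leucine-zipper factor Tsc22d3 (1.52), at a list median of 0.98 (camera adjusted p = 9.70e-23, adjusted p = 0.367 with an estimated correlation). Ddit4 and the vasoactive peptide gene Adm (1.29) and mitophagy receptor Bnip3 (1.28) were the 3 of 11 hypoxia-response genes that rose. When adjusted over the list alone 4 rose and 3 fell (list median 0.14, adjusted p = 0.367 with an estimated correlation). The clock gene Per2 (1.72) was the sole circadian gene of 15 to rise (2 when adjusted over the list alone; adjusted p = 0.397 with an estimated correlation). Without cold replicate 1 the circadian list (median 0.14) and the calls of Dnajb1 (1.77), Dusp1 (1.57), Glul (1.57), Tsc22d3 (1.38), Pdk4 (2.63), Adm (1.28), Bnip3 (1.06) and Per2 (1.52) ended. So did those of Dusp1 (1.43), Bnip3 (1.47) and Per2 (1.90) without cold replicate 2 and of Bnip3 (1.05) without room-temperature replicate 2.

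The interferon response list was lower in cold fibroblasts (2 of 17 fell, Irf7 at -1.51 and Bst2 at -1.06; 9 when adjusted over the list alone; adjusted p = 0.397 with an estimated correlation). The inflammatory cytokines were lower as well (3 of 10 fell; 4 when adjusted over the list alone; adjusted p = 0.367 with an estimated correlation). The called cytokine genes were the monocyte chemokine Ccl2 (-0.88), the alarmin Il33 (-0.96) and Cxcl2 (-1.08), the last at under 5% of its level in neutrophils. Within the 6 clusters of the class, with no test, the median log2 ratio of mean CPM ran from -1.54 to 0 for the interferon list and from -1.53 to 0.76 for the inflammatory cytokines. In the unfolded protein response list 5 of 16 fell, with the endoplasmic reticulum chaperones Hsp90b1 (-1.07), Calr (-1.01), Pdia6 (-0.93) and Pdia4 (-0.91). When adjusted over the list alone 7 fell and 1 rose (adjusted p = 0.426 with an estimated correlation). The cholesterol synthesis list was lower with 0 of 20 members past the edgeR threshold over all genes and 8 lower when adjusted over the list alone (adjusted p = 0.397 with an estimated correlation). The mitosis (G2 and M phase) list was lower with 0 of 8 and 7 (adjusted p = 0.397 with an estimated correlation). Without cold replicate 1 the count of 336 changed genes became 4, and of the 46 named called genes 3, Ddit4, Hspa1a and Col18a1, still passed. The count was 112 without cold replicate 2, where 26 of the 46 passed and the unfolded protein list lost its call (median -0.22), 171 without room-temperature replicate 2 and 1490 without the low-count filter. Without cold replicate 2 the calls of Irf7 (-1.65), Bst2 (-1.05), Ccl2 (-0.98), Il33 (-1.06), Cxcl2 (-1.29), Hsp90b1 (-0.98), Calr (-0.84), Pdia6 (-0.83) and Pdia4 (-0.71) ended. So did that of Pdia4 (-0.97) without room-temperature replicate 1, and without room-temperature replicate 2 those of Il33 (-0.76), Cxcl2 (-0.88), Calr (-0.84) and Pdia4 (-0.84).

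**Figure D2:**
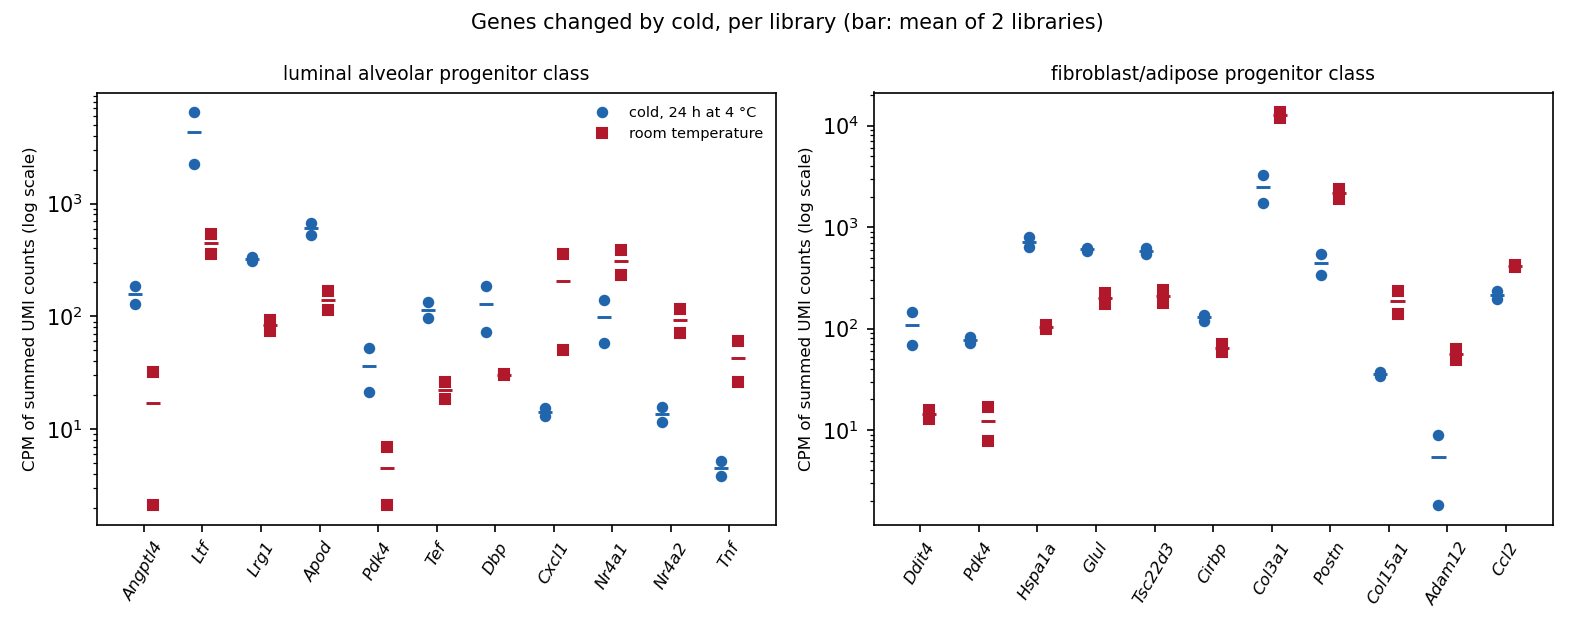
CPM of UMI counts summed per class and library on a log axis, for genes called in luminal alveolar progenitors (left) and fibroblasts and adipose progenitors (right). Points are libraries and bars are means of the 2 libraries of a group. Col3a1 in fibroblasts stood at 1718 and 3236 CPM in cold and 11904 and 13581 CPM at room temperature. Lrg1 in alveolar progenitors stood at 336 and 307 CPM in cold and 73.9 and 92.4 CPM at room temperature.

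In luminal hormone-sensing cells, the most deeply covered epithelial class with 140 to 509 cells and 3753239 to 13772968 UMIs per library, Nrg4, Angptl4, Enho and Lrg1 stood higher in both cold libraries without passing the test. Nrg4 (ENSMUSG00000032311, chromosome 9, 55220222 to 55326844), a secreted neuregulin, was singled out after its values were seen. It stood at 369 and 223 CPM in cold and 41.1 and 57.8 CPM at room temperature (log2 fold change 2.65, SE 0.30, edgeR quasi-likelihood adjusted p = 0.316). Angptl4 stood at 123 ± 12.0 CPM in cold and 34.7 ± 8.40 CPM at room temperature (log2 fold change 1.83, SE 0.23, adjusted p = 0.338). Enho, which encodes the peptide adropin, stood at 373 ± 101 CPM in cold and 209 ± 10.7 CPM at room temperature (log2 fold change 0.88, SE 0.22, adjusted p = 0.411). Lrg1 stood at 58.2 ± 37.0 CPM in cold and 15.4 ± 6.29 CPM at room temperature. Of 15 secreted regulators measured, 0 passed over all genes, 3 rose and 2 fell when adjusted over the list alone. The list had a median of -0.54 and mean of -0.12 with a test direction upward (camera adjusted p = 0.576). Among 12755 genes tested 1 was called, the haemoglobin gene Hbb-bs (ENSMUSG00000052305, chromosome 7, 103826534 to 103828096). It stood at 98.3 ± 6.15 CPM in cold and 2.41 ± 0.392 CPM at room temperature (log2 fold change 5.29, SE 0.19, adjusted p = 0.0122). In cold replicate 1 a single cell held 1215 of its 1228 UMIs, and in cold replicate 2 the highest cell held 883 of 1196, so a few cells carry the value. Its reads cannot be parted with certainty from those of the near-identical Hbb-bt.

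At an unadjusted p under 0.05 the class had 1465 genes, and DESeq2 called 125 at its adjusted threshold, Angptl4 among them (adjusted p = 1.79e-08). Without the low-count filter edgeR called 141, at Leiden resolution 2 it called 2, without cold replicate 2 38, without room-temperature replicate 1 2 and without room-temperature replicate 2 4. The camera test called 15 lists in these cells, all with 0 members past the edgeR threshold over all genes. The inflammatory cytokine list had a median of -2.10 with 6 of 11 members lower when adjusted over the list alone. Of its 11 members, 6 lay under 5% of their level in the class that holds most of them. The interferon list had a median of -1.09 with 8 of 17 lower (each adjusted p = 0.443 with an estimated correlation). The MHC class II and matrix lists fell as well, each with most members at under 5% of their level in the class that holds most of them. The MHC class II list had a median of -2.28 with 4 of 6 lower and 5 of 6 at such levels. The matrix list had a median of -1.66 with 10 of 19 lower and 18 of 19 at such levels (each adjusted p = 0.443 with an estimated correlation). The mitosis list had a median of -2.11 with 0 of 19 members past the threshold when adjusted over the list alone (adjusted p = 0.546 with an estimated correlation). The circadian clock list was higher at a median of 0.55, with 1 of 16 members higher when adjusted over the list alone (adjusted p = 0.443 with an estimated correlation). In room-temperature replicate 1 the largest cluster of the class was led by Upk3a and Fgb, and in the other libraries by Prlr and Wfdc2. The Prlr-led cluster held 92.3% and 74.7% of the class in cold and 19.1% and 70.7% at room temperature. Within the Prlr-led cluster and both Upk3a-led clusters, the last over 2 libraries, with no test, the median log2 ratio of mean CPM was -0.02, 0.34 and -0.61 for the interferon list and -0.31, -0.17 and -0.27 for the mitosis list. For the inflammatory cytokines it was -0.43, -1.22 and -1.04, for the circadian clock 0.35, 0.39 and 0.22 and for the stress list 0.55, 0.10 and -0.24. Within the Prlr-led cluster, with 87 to 470 cells per library, Nrg4 stood at 399 and 320.0 CPM in cold and 126 and 90.1 CPM at room temperature. In the larger Upk3a-led cluster it stood at 132 and 41.9 CPM in cold and 37.7 and 27.1 CPM at room temperature. In the smaller one it stood at 9.4 CPM in cold replicate 2 and 14.3 CPM in room-temperature replicate 1, the libraries with 20 or more of its cells.

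Whether cold acted differently on the epithelial and stromal classes was tested as a class by temperature term. Between alveolar progenitors and fibroblasts the effect differed for 196 of 12002 genes, 85 with a higher and 111 with a lower change in alveolar progenitors (edgeR quasi-likelihood, Benjamini-Hochberg). The stress list separated these classes: 14 of its 20 members had a lower change in alveolar progenitors, 20 when adjusted over the list alone (median difference -1.72, adjusted p = 0.789 by camera with an estimated correlation). This was not particular to alveolar progenitors, since the list had a lower change in hormone-sensing cells than in fibroblasts too (median difference -1.37). Map2, a microtubule-associated protein, stood in alveolar progenitors at 207 and 179.7 CPM in cold and 69.3 and 110.0 CPM at room temperature. In fibroblasts it stood at 0.990 and 0.550 CPM in cold and 4.33 and 15.0 CPM at room temperature (adjusted p = 5.62e-12 for the difference). Hey1, a Notch target that rose in alveolar progenitors, stood there at 348 and 239.6 CPM in cold and 92.4 and 79.7 CPM at room temperature, against at most 2.84 CPM in any fibroblast library. Cyp2f2 rose in fibroblasts, and stood in alveolar progenitors at 9.67 and 0 CPM in cold and 4.62 and 21.1 CPM at room temperature (adjusted p = 3.10e-06 for the difference). For Map2, Hey1 and Cyp2f2, and for Itga8, Papln, Col18a1, Tubb6, Gfpt2, Cyp1b1 and Lsmem1, also among the largest differences, 1 of the classes lay at or below 13.6 CPM on average, where a fitted fold is no bound. The count was 32 without cold replicate 1 and 129 without cold replicate 2; Cyp2f2 did not pass without room-temperature replicate 2, nor Itga8 without cold replicate 1. Col18a1, Tubb6, Gfpt2, Cyp1b1 and Lsmem1 did not pass without cold replicate 1 either, nor Gfpt2 without cold replicate 2 or room-temperature replicate 1, nor Itga8 and Cyp1b1 without room-temperature replicate 2.

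Between hormone-sensing and alveolar cells the cold effect differed for 154 of 11499 genes, 30 with a higher and 124 with a lower change in hormone-sensing cells (edgeR quasi-likelihood, Benjamini-Hochberg). Apod stood in hormone-sensing cells at 1.76 and 1.89 CPM in cold and 12.6 and 8.79 CPM at room temperature. In alveolar cells it stood at 528 and 677 CPM in cold and 166 and 113 CPM at room temperature (adjusted p = 7.25e-12 for the difference). Ncald, a neuronal calcium sensor, stood at 0.330 and 0.710 CPM in cold and 2.32 and 4.00 CPM at room temperature in hormone-sensing cells. It stood at 159 and 115 CPM in cold and 39.3 and 101 CPM at room temperature in alveolar cells (adjusted p = 1.40e-04 for the difference). The hormone-sensing levels of both genes are too low for a bounded fold. Piezo2, a mechanosensitive ion channel, stood in hormone-sensing cells at 137 and 130.4 CPM in cold and 95.9 and 58.1 CPM at room temperature. In alveolar cells it stood at 1.93 and 0 CPM in cold and 30.03 and 16.2 CPM at room temperature, too few UMIs for a bounded fold. Of 13 milk and secretory genes, 8 had a lower change in hormone-sensing cells, 10 when adjusted over the list alone (median difference -1.76, adjusted p = 0.653 by camera with an estimated correlation). Of the 10 tested within hormone-sensing cells, 6 lay under 5% of their level in the class that holds most of them. Within the clusters of that class, with no test, the median log2 ratio of the list was 0.08, -0.13 and, over 2 libraries, 0.30. Gsta4, Noct, Lalba, Sectm1b and Aldh3b1 also passed, each with a class at or near 0 CPM in 1 or more libraries. Gsta4 lost its call with any library left out, Noct without cold replicate 1, Lalba and Sectm1b without cold replicate 2 or room-temperature replicate 2, and Aldh3b1 with any library but cold replicate 1 left out. Lalba turned to 0.28 without room-temperature replicate 2, and the count was 61 without cold replicate 1 and 251 without room-temperature replicate 2.

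Between hormone-sensing cells and fibroblasts the cold effect differed for 4 of 13859 genes. At an unadjusted p under 0.05 this pair had 1495 genes, against 1203 for hormone-sensing and alveolar cells and 1172 for alveolar cells and fibroblasts. The stress list had a lower change in hormone-sensing cells, with 0 of 20 members past the threshold over all genes. When adjusted over the list alone 15 were lower and 0 higher (median difference -1.37, adjusted p = 0.657 by camera with an estimated correlation). Ddit4 stood at 18.6 and 22.9 CPM in cold and 23.0 and 23.2 CPM at room temperature in hormone-sensing cells. It stood at 69.2 and 146 CPM in cold and 15.9 and 12.9 CPM at room temperature in fibroblasts (difference -2.93, SE 0.29, adjusted p = 0.0261, edgeR quasi-likelihood). Edn1, the vasoconstrictor peptide endothelin 1, rose in fibroblasts, at 259 and 353 CPM in cold and 104 and 85.2 CPM at room temperature. In hormone-sensing cells it stood at 2.84 and 3.85 CPM in cold and 6.17 and 6.13 CPM at room temperature (adjusted p = 0.0261 for the difference), too low for a bounded fold. The remaining genes were Apod, with at most 12.6 CPM in hormone-sensing cells, and Hbb-bs, whose UMIs lay in a few cells. The count was 383 without the low-count filter, 8 without cold replicate 1, 230 without cold replicate 2, 7 without room-temperature replicate 1 and 315 without room-temperature replicate 2. Without room-temperature replicate 1 the differences of Ddit4 (adjusted p = 0.0866), Edn1 (adjusted p = 0.0886), Apod (adjusted p = 0.0694) and Hbb-bs (adjusted p = 0.168) did not pass, nor did that of Apod without cold replicate 1 (adjusted p = 0.0656).

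Ucp1 (ENSMUSG00000031710, chromosome 8, 83290352 to 83298452), the uncoupling protein of thermogenic adipocytes, had 3 and 8 UMIs in the cold libraries and 5 and 3 at room temperature, so a cold effect on it was not detectable at this depth. The adipocyte hormone Adipoq had 15, 16, 34 and 9 UMIs and the β3-adrenergic receptor Adrb3 had 2, 0, 3 and 0 in the same order, where a count of 0 allows up to 3 UMIs by counting error alone. Lcn2, the secreted iron-scavenging lipocalin, stood in alveolar progenitors at 3549.8 ± 59.0 CPM in cold and 2197 ± 973 CPM at room temperature (log2 fold change 0.57, SE 0.31, adjusted p = 0.404, edgeR quasi-likelihood). In hormone-sensing cells it stood at 53.5 ± 60.1 CPM in cold and 151 ± 32.0 CPM at room temperature (log2 fold change -1.48, SE 0.91, adjusted p = 0.539). Only 11.0% and 10.9% of those cells in cold and 18.7% and 15.0% at room temperature had an Lcn2 UMI, so a minority carries the value. Adrb1, the β1-adrenergic receptor, stood in hormone-sensing cells at 36.5 ± 0.801 CPM in cold and 24.4 ± 12.2 CPM at room temperature (log2 fold change 0.69, SE 0.31, adjusted p = 0.453). The α2A receptor Adra2a stood at 30.9 ± 15.3 CPM in cold and 23.1 ± 2.54 CPM at room temperature (log2 fold change 0.43, SE 0.36, adjusted p = 0.648). Adra1a stood there at 7.58 ± 0.276 CPM in cold and 25.9 ± 30.5 CPM at room temperature. Cirbp passed in NK/innate lymphoid cells (log2 fold change 0.90, SE 0.22, adjusted p = 0.0143) and T cells (log2 fold change 0.60, SE 0.13, adjusted p = 0.0447) besides fibroblasts. Rbm3 passed in none of the 10 classes, its smallest adjusted p being 0.0621. It lay higher in both cold libraries in each tested class but the alveolar and hormone-sensing ones. Camera called the list of 3 cold-inducible RNA-binding proteins higher in fibroblasts, macrophages, NK/innate lymphoid, dendritic, hormone-sensing, pericyte and vascular endothelial cells. That list was not called in alveolar, T or B cells, nor in any class with an estimated correlation. Cirbp lost its call in T cells without cold replicate 1 (0.45) and room-temperature replicate 1 (0.59), in fibroblasts without either cold library (1.12 and 0.99), and in NK/innate lymphoid cells with any library left out (0.82 to 0.94).

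In macrophages and monocytes, Ddit4 rose from 7.87 ± 0.639 to 134 ± 3.31 CPM (log2 fold change 4.08, SE 0.14, adjusted p = 7.13e-04, edgeR quasi-likelihood). The anti-inflammatory cytokine Il10 (log2 fold change -3.16, SE 0.23, adjusted p = 0.0193), the monocyte chemokine Ccl7 (log2 fold change -2.42, SE 0.13, adjusted p = 0.0065), the interleukin-1 receptor antagonist Il1rn (-2.37) and Il6 (-2.05) fell. Of 11278 genes 4 rose and 16 fell over all clusters of the class together. The largest cluster was led by C1qa and C1qc in both cold libraries and by C1qa and C1qb in both room-temperature libraries. Within the 4 clusters with 20 or more cells in each library, with no test, the median log2 ratio of mean CPM ran from -1.33 to -0.14 for the inflammatory cytokines and was at most -0.52 for the interferon list. Of 13 inflammatory cytokine genes 3 fell, and when adjusted over the list alone 9 fell and 1 rose (median -0.97, adjusted p = 0.22 with an estimated correlation). Of 17 interferon-response genes 2 fell, 15 when adjusted over the list alone (median -1.22, adjusted p = 0.399 with an estimated correlation). Matrix transcripts had a median of -1.91, with 0 of 19 past the edgeR threshold over all genes and 14 lower when adjusted over the list alone (adjusted p = 0.399 with an estimated correlation). Of the 19, 18 lay under 5% of their level in the class that holds most of them. Ly6d (1.22) was likewise at under 5% of its level in hormone-sensing cells. The count of 20 was 188 with DESeq2, 811 without the low-count filter, 46 with doublets kept, 37 with the looser cell filter and 46 at Leiden resolution 2. It was 1 without cold replicate 1, 2 without cold replicate 2, 158 without room-temperature replicate 1 and 127 without room-temperature replicate 2. Of the 7 named genes called, Ddit4 alone passed without either cold library, where Il10 stood at -2.98 and -3.33 and Ccl7 at -2.49 and -2.36.

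In T cells 80 genes rose and 220 fell of 9967, over all clusters of the class together. The largest cluster was led by Ccl5 and Cd8b1 in both cold libraries and by Trbc2 and Dapl1 in both room-temperature libraries. Within the 4 clusters, 1 of them over 3 libraries, with no test, the median log2 ratio of mean CPM ran from -1.09 to 0.25 for the cAMP-response list, from -0.14 to 0.23 for the mitosis list and from -2.37 to -1.84 for the matrix list. Hspa1a (log2 fold change 2.97, SE 0.43, adjusted p = 0.0076, edgeR quasi-likelihood), Hspa1b (2.37), Ddit4 (1.97) and the growth regulator Myc (1.78) rose. Ramp3 (log2 fold change -1.79, SE 0.14, adjusted p = 0.0012), a receptor-activity modifier, AI480526 (-2.05) and the triglyceride synthesis enzyme Dgat1 (-1.61) fell. Of 13 cAMP-response genes 8 fell, 9 when adjusted over the list alone (median -0.95, adjusted p = 0.379 with an estimated correlation). Of 19 mitosis genes 5 rose, 12 when adjusted over the list alone (median 0.55, adjusted p = 0.49 with an estimated correlation). Matrix transcripts were lower, 3 of 9 over all genes and 9 when adjusted over the list alone (median -2.28, adjusted p = 0.49 with an estimated correlation). All 9 lay under 5% of their level in the class that holds most of them. Col3a1 stood at 6.57 ± 3.58 CPM in cold and 69.0 ± 48.6 CPM at room temperature. DESeq2 called 188 genes, Hspa1a not among them (adjusted p = 0.0622), edgeR without the low-count filter 974, and edgeR without cold replicate 1 626.

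NK and innate lymphoid cells, with 46 to 167 cells per library, had 52 genes higher and 49 lower of 4949. Hspa1a (log2 fold change 3.24, SE 0.31, adjusted p = 6.23e-11, edgeR quasi-likelihood), Hspa1b (3.14), the adhesion receptor Crtam (2.36) and the interferon-inducible Ifi206 (2.18) rose. The antigen-presentation genes H2-Aa (-2.74), Cd74 (-2.38) and H2-Eb1 (-2.36) and the collagen gene Col3a1 (-4.10) fell, at under 5% of their level in dendritic cells and fibroblasts respectively. In dendritic cells Hspa1a (log2 fold change 2.72, SE 0.18, adjusted p = 0.0033), Hspa1b (2.76), the AP-1 factor Jun (2.58) and the chemokine Ccl4 (2.49) rose. Plek (-1.42), Nr4a3 (-1.32) and the cytokine Il1b (-1.27) fell, among 12 genes higher and 3 lower of 8130. In B cells Jun (log2 fold change 1.80, SE 0.27, adjusted p = 0.0223), the signalling regulator Rgs1 (1.82) and Ppp1r21 (1.65) rose. Col1a2 (-2.79) and Fn1 (-2.75) fell at under 5% of their fibroblast level, among 4 genes higher and 2 lower of 6583. The stress list was higher in NK/innate lymphoid cells (7 of 19 rose, 10 when adjusted over the list alone; adjusted p = 0.237 with an estimated correlation). It was also higher in dendritic (6 of 19 rose; 12 rose and 1 fell when adjusted over the list alone; adjusted p = 0.455 with an estimated correlation) and B cells (1 of 19 rose, 6 when adjusted over the list alone; adjusted p = 0.557 with an estimated correlation). The pan-epithelial list was called higher in dendritic cells (median 1.38; 3 of 5 rose when adjusted over the list alone; adjusted p = 0.455 with an estimated correlation), with 4 of the 5 at under 5% of their level in the class that holds most of them. It was also called higher in fibroblasts (median 0.74, 1 of 8 rose, 3 when adjusted over the list alone, camera adjusted p = 0.367 with an estimated correlation). The same held in macrophages (median 0.63, 0 of 8 rose, 0 when adjusted over the list alone, camera adjusted p = 0.669 with an estimated correlation). All 8 members lay at such low levels in each of these classes. The macrophage call ended without cold replicate 1 (median 0.16) or room-temperature replicate 2 (median 0.47). DESeq2 called 17 genes in NK/innate lymphoid and 44 in dendritic cells. In NK/innate lymphoid cells Hspa1b and H2-Aa passed with DESeq2. Hspa1a (adjusted p = 0.229), Cd74 (adjusted p = 0.824), Cirbp (adjusted p = 0.359) and H2-Eb1 did not, and Crtam, Ifi206 and Col3a1 had no adjusted p there. Without room-temperature replicate 1 the counts were 39 in NK/innate lymphoid, 6 in dendritic and 2 in B cells, and without replicate 2 53 in NK/innate lymphoid and 170 in dendritic cells. They were 102 and 128 in dendritic and B cells without cold replicate 1, and 157 and 214 without cold replicate 2. The calls of Crtam (1.76) and Ifi206 (0.94) ended without cold replicate 2. Without room-temperature replicate 1 those of Crtam (2.80) and Ifi206 (2.26) in NK/innate lymphoid, Plek (-1.40), Nr4a3 (-1.32) and Il1b (-1.12) in dendritic and Jun (2.37), Rgs1 (2.64), Ppp1r21 (1.68) and Col1a2 (-2.78) in B cells ended. Without room-temperature replicate 2 those of Crtam (1.81), Jun (1.46), Rgs1 (1.48) and Ppp1r21 (1.62) ended. The B-cell stress list lost its call without cold replicate 1 (median 0.01). At Leiden resolution 2, 0 of the 5 named B-cell genes and 4 of the 7 named dendritic-cell genes passed, as did 4 of the latter with doublets kept or the looser cell filter.

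In vascular endothelial cells 2 of 10170 genes rose and 0 fell. The secreted protein gene Cytl1 stood at 54.3 ± 0.798 CPM in cold and 1.39 ± 0.335 CPM at room temperature (log2 fold change 5.23, SE 0.31, adjusted p = 0.0128, edgeR quasi-likelihood), and the phosphatase Dusp8 at 50.4 ± 1.41 CPM in cold and 7.27 ± 0.473 CPM at room temperature (log2 fold change 2.80, SE 0.23, adjusted p = 0.0496). An unadjusted p under 0.05 was reached by 1047 genes, and DESeq2 called 79. Of 20 stress genes 0 passed over all genes and 19 rose when adjusted over the list alone (median 1.25, adjusted p = 0.399 with an estimated correlation). Of 17 glucocorticoid-response genes 0 passed over all genes and 11 rose when adjusted over the list alone (median 0.81, adjusted p = 0.399 with an estimated correlation). The interferon list was lower, with 11 of 17 members when adjusted over the list alone (median -0.70, adjusted p = 0.399 with an estimated correlation). Angptl4 stood at 554 ± 1.68 CPM in cold and 207 ± 85.5 CPM at room temperature (log2 fold change 1.45, SE 0.26, adjusted p = 0.166) without passing. In pericytes and smooth muscle cells, with 24 to 58 cells per library, the edgeR quasi-likelihood test called 0 of 3465 genes. An unadjusted p under 0.05 was reached by 192, and DESeq2 called 1. Angptl4 stood at 598 ± 53.7 CPM in cold and 112 ± 132 CPM at room temperature (log2 fold change 2.31, SE 0.60, adjusted p = 0.878). With doublets kept or the looser cell filter, neither Cytl1 (3.21 and 2.55) nor Dusp8 passed. With the replicate number as a block, 1 of these 2 genes passed. Leaving out cold replicate 1, cold replicate 2, room-temperature replicate 1 or 2 gave 35, 29, 462 and 14 genes in vascular endothelial cells and 75, 48, 115 and 17 in pericytes and smooth muscle cells. Over the 10 classes, camera called 106 of 243 list tests with the preset correlation and 0 with an estimated correlation, where 13 had an unadjusted p under 0.05 and the smallest adjusted p was 0.22.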

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

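The tests of the stress genes, the comparison of depth between classes and the refits of part of the hormone-sensing class were chosen only after the result was seen. Between classes, the test of the difference in cold effect itself passed for 154 genes in hormone-sensing against alveolar cells, 4 in hormone-sensing cells against fibroblasts and 196 in alveolar cells against fibroblasts. At an unadjusted p under 0.05 the pairs had 1203, 1495 and 1172 genes in the same order, so the counts past the threshold do not rank them. Of the genes named there, the difference in log2 fold change, hormone-sensing minus alveolar, was -4.48 for Apod and -3.41 for Ncald. Hormone-sensing minus fibroblast, it was 5.36 for Hbb-bs, -2.93 for Ddit4, -2.79 for Apod and -2.51 for Edn1, none of which passed without room-temperature replicate 1. Alveolar minus fibroblast, it was 4.35 for Map2 and 3.41 for Itga8, where Itga8 did not pass without cold replicate 1 (1.93) or room-temperature replicate 2 (3.13). For each of these genes but Ddit4, 1 class lay at or below 6.25 CPM on average, so the fitted size is no bound.

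Matrix transcripts such as Col3a1 were lower with cold in T cells, B cells and macrophages, classes that do not make most of them. Doublets with fibroblasts are argued against: the 1% of room-temperature T cells with most matrix UMIs held 4.9% and 8.1% of them in the 2 libraries, and 76.2% and 59.0% of T cells had such a UMI. In cold, where such UMIs were fewer, the share was 26.2% and 14.7%. Free RNA from fibroblasts may account for the pattern, since over 35 gene and class values the change in the class lay a median of -0.24 (quartiles -0.82 to 0.06) from the change in the whole library, and 34 of the 35 lay under 5% of the level in the top class. A lower output of matrix RNA by these classes themselves stays open, untested.

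The list of heat shock and immediate early genes was higher with cold in 8 of 10 classes by camera and lower in alveolar cells. No class was called at an estimated correlation. The heat shock genes themselves did not pass in alveolar cells. The log2 fold change there was 0.03 for Hspa1a, 0.21 for Hspa1b, -0.38 for Dnajb1, -0.53 for Hspb1, -0.66 for Hspa8 and -1.12 for Hsp90aa1. The hormone-sensing class was called lower too, but not without room-temperature replicate 1, and within its clusters, with no test, the median log2 ratio was 0.55, 0.10 and, over 2 libraries, -0.24. A handling difference acting alike on all cells of a library is argued against, since 14 of the 20 genes differed in their change between alveolar cells and fibroblasts. A handling difference that acts unlike on the classes stays open, untested, because the labels give no day or batch of dissociation. Cold exposure through glucocorticoid-type induction could also account for it, though undecided here: the glucocorticoid list was higher in 5 of the 8 classes and lower in none (0), and handling and cold exposure cannot be told apart because both follow the groups.

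The hormone-sensing class gave 1 called gene in spite of its depth. Low depth is argued against, since the alveolar class, with fewer UMIs in each library, gave 131. A mixture of cell states that differs between libraries stays open. The largest cluster alone gave 1 gene, Hbb-bs again, but from only 87 and 99 cells at room temperature. The medians of the mitosis and S-phase lists, -2.11 and -1.12 over the class, were -0.31 and 0.02 within that cluster, with no test. Doublets with alveolar cells as the only cause are argued against, since leaving out cells with alveolar markers gave 1 gene. That refit cannot decide whether doublets played a part beside a mixture of states. It kept 389 of 455 cells in room-temperature replicate 1, where the largest cluster held 87, so the mixture stayed. Spread between the libraries themselves stays open: the biological coefficient of variation was 0.210 against 0.180 in alveolar cells. DESeq2 called 125 genes here and 61 in alveolar cells, the reverse order of the edgeR counts. The edgeR counts of 1 and 131 therefore depend on the test and do not measure which class responded more to cold.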

How the results depend on the processing

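The alternatives without possible free RNA genes, with the largest hormone-sensing cluster alone and without hormone-sensing cells that carry alveolar markers were chosen only after the result was seen. In the edgeR quasi-likelihood test of all 4 libraries the genes called numbered 336 in fibroblast, 131 in alveolar, 1 in hormone-sensing, 20 in macrophage, 300 in T, 6 in B, 15 in dendritic, 101 in NK/innate lymphoid, 2 in vascular endothelial and 0 in pericyte cells. Counts within 1.5 times these are left out of what follows. With DESeq2 they were 61 in alveolar, 125 in hormone-sensing, 188 in macrophage, 188 in T, 44 in dendritic, 17 in NK/innate lymphoid, 79 in vascular endothelial and 1 in pericyte cells. These split 11 up and 6 down in NK/innate lymphoid, 27 up and 17 down in dendritic, 61 up and 64 down in hormone-sensing and 66 up and 13 down in vascular endothelial cells. With no low-count filter they were 1490 in fibroblast, 349 in alveolar, 141 in hormone-sensing, 811 in macrophage, 974 in T, 105 in B, 287 in dendritic, 69 in vascular endothelial and 72 in pericyte cells. With doublets kept they were 46 in macrophage, 0 in vascular endothelial and 8 in pericyte cells. The looser cell filter gave 37 in macrophage, 11 in B, 5 in dendritic, 0 in vascular endothelial and 2 in pericyte cells, and Leiden resolution 2 gave 31 in alveolar, 2 in hormone-sensing, 46 in macrophage, 0 in B and 10 in vascular endothelial cells. Without possible free RNA genes the hormone-sensing count was 0, since that alternative leaves out Hbb-bs. RLE scaling kept each count within 1.5 times and, like DESeq2, moved the median of all genes by at most 0.00860 on the log2 scale. Leaving out each library in turn gave lowest and highest counts of 4 and 421 in fibroblast, 83 and 508 in alveolar, 1 and 38 in hormone-sensing, 1 and 158 in macrophage, 243 and 626 in T, 2 and 214 in B, 6 and 170 in dendritic, 39 and 97 in NK/innate lymphoid, 14 and 462 in vascular endothelial and 17 and 115 in pericyte cells. The number of lists called fell to 0 in all 10 classes with an estimated correlation. With a library left out, it lay between 16 and 19 in fibroblast (from 17), 9 and 11 in alveolar (from 9), 12 and 17 in hormone-sensing (from 15), 8 and 16 in macrophage (from 12), 5 and 11 in T (from 7), 5 and 12 in B (from 7), 7 and 12 in dendritic (from 11), 5 and 7 in NK/innate lymphoid (from 4), 10 and 15 in vascular endothelial (from 11) and 8 and 12 in pericyte (from 13) cells. For the difference in cold effect, leaving out a library gave 61 to 251 genes for hormone-sensing minus alveolar (from 154), 7 to 315 for hormone-sensing minus fibroblast (from 4, and 383 with no low-count filter) and 32 to 247 for alveolar minus fibroblast (from 196). No share passed under any alternative but leaving out a library: the basal share lay between -2.16 and -0.52 on the log2 scale and passed without room-temperature replicate 1 (-2.16), as did the hormone-sensing share, between 0.78 and 1.71, at 1.71. Results turned direction in 5 cases, none of them past the threshold then. They were, without cold replicate 1 the inflammatory list in B cells (median 0.26, the test turned; 0.11 to 0.56 over the libraries left out), without cold replicate 2 the interferon list in T cells (-0.26; -0.26 to 1.51 over the libraries left out), without room-temperature replicate 1 the stress list in hormone-sensing cells (0.043; -0.75 the lowest over the libraries left out) and the adipocyte list in pericytes (0.70, the test turned; 0.46 to 0.75 over the libraries left out), and without room-temperature replicate 2 the Lalba difference between hormone-sensing and alveolar cells (0.28; -7.05 to 0.28 over the libraries left out). Of the named genes called, 23 lost their call with DESeq2, 28 at resolution 2, 10 with doublets kept, 10 with the looser filter and 1 with no low-count filter. Leaving out cold replicate 1, 63 lost it; leaving out cold replicate 2, 34; leaving out room-temperature replicate 1, 15; and leaving out replicate 2, 16. The cause was not tested. Libraries share replicate numbers and no label pairs them. With the number as a block the counts were 802 in fibroblast, 928 in macrophage, 1179 in T, 42 in B, 77 in dendritic, 186 in NK/innate lymphoid and 6 in vascular endothelial cells, and 3 named genes and 2 lists did not pass. The correlation across genes of the deviations of replicate 1 in both groups ran from -0.203 (hormone-sensing) to 0.385 (macrophage) in the 10 classes, over genes that are not independent. At Leiden resolution 2 the pericyte class has no value, with under 20 cells in a library. Depth was lowest in the pericyte class, with 157979 UMIs in its smallest library and 3465 genes tested.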

Other observations

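All values here were picked after the data were seen, and those of basal cells carry no test. In basal/myoepithelial cells Hspa1a, the inducible HSP70 chaperone, stood at 1408 and 547 CPM in cold and 80.4 and 80.5 CPM at room temperature. Angptl4, the lipoprotein lipase inhibitor, stood at 472 and 575 CPM in cold and 301 and 95.6 CPM at room temperature. Pdk4, the kinase that restrains glucose oxidation, stood at 144 and 269.5 CPM in cold and 109 and 61.5 CPM at room temperature. The basal keratin Krt14 stood at 3442 and 2873 CPM in cold and 1269 and 1303 CPM at room temperature. Of other basal markers, Krt5 stood at 710.1 and 594 CPM in cold and 885 and 659.7 CPM at room temperature and Oxtr at 397 and 344 CPM in cold and 429.5 and 362 CPM at room temperature, neither higher on average in cold. Lcn2 stood there at 2747 ± 617 CPM in cold and 714 ± 62.0 CPM at room temperature.

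Members of lists are counted here after adjustment over the list alone. In pericytes and smooth muscle cells camera called 13 lists with 0 members past the edgeR quasi-likelihood threshold over all genes. The secreted regulators, which include Angptl4, were higher (median 1.07; 3 higher and 0 lower of 6; adjusted p = 0.311 with an estimated correlation). So was the glucocorticoid response (median 0.90; 3 higher and 0 lower of 13; adjusted p = 0.311 with an estimated correlation). The stress genes were higher there too (median 1.21; 3 higher and 0 lower of 20; adjusted p = 0.311 with an estimated correlation). Larger medians there were those of the inflammatory cytokines (median 2.64; 3 higher and 0 lower of 3; adjusted p = 0.311 with an estimated correlation) and MHC class II (median 2.12; 4 higher and 0 lower of 4; adjusted p = 0.336 with an estimated correlation). The MHC class II call ended without cold replicate 2 (median 0.51). In vascular endothelial cells the secreted regulators (median 0.80; 4 higher and 1 lower of 17; adjusted p = 0.487 with an estimated correlation) and the cAMP-response genes (median 0.98; 8 higher and 0 lower of 13; adjusted p = 0.399 with an estimated correlation) were higher. In hormone-sensing cells the milk and secretory genes were called lower (median -1.10; 0 higher and 0 lower of 10; adjusted p = 0.443 with an estimated correlation). Of these 10 genes, 6 lay under 5% of their level in the class that holds most of them. The S-phase genes were called lower as well (median -1.12; 0 higher and 0 lower of 18; adjusted p = 0.606 with an estimated correlation). Within the clusters of that class, with no test, the median log2 ratio was 0.08, -0.13 and 0.30 for the milk and secretory genes and 0.02, 0.01 and -0.01 for the S-phase genes. In macrophages the glucocorticoid response was higher (median 0.21; 4 higher and 2 lower of 17; adjusted p = 0.399 with an estimated correlation).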
